A study of Homo sapiens with 2 samples.

How the data were processed

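Total RNA of MCF-10A cells was extracted, cleaned and treated with DNase, its quality was checked, and biotin-labelled cRNA was made with an Illumina amplification kit, per the labels' protocols. The labels put 1 array in each group, negative control siRNA and SCTR siRNA, 2 arrays in all. The non-normalized table deposited by the authors gives for each of 47323 probes an intensity and a detection p-value per array, and GenomeStudio 2011.1 is named for it in the submitters' processing notes. A signal was present for 47316 probes and absent for 7, which were left out. Negative intensities did not occur (lowest 64.3 and 61.1), so the values were taken as not background-subtracted. Detection p-values moved in steps of 0.0013, which sets how finely a dim probe can be told from background. The lowest normalized log2 level among detected probes was 6.04 on the control array and 5.91 on the SCTR siRNA array.

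The authors' processed table holds log2 values for 16871 probes. Set against the log2 intensities of the same array they correlated with r = 1.00 on both, so the scale is log2 without background correction. Both columns hold the same sorted values within 0.000416 and have a median of 8.57, as quantile normalization gives, and each probe in the table had a detection p under 0.05 on at least 1 array. They differed by up to 0.102 from the mean of the sorted log2 intensities of both arrays, and the exact steps are not given in the sources used here. Each column is a level and not a ratio, and which array is which rests on the labels.

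Gene symbols came from a table of platform annotation for the probes of the processed table. Of these, 13060 had 1 symbol, 3 had several and were left unnamed, and 3808 had no name there. Gene IDs of 13054 probes matched a RefSeq gene table (assembly GRCh38.p14), which changed 0 symbols and was used for names only. Probes outside the processed table carry no name here. In total 10161 symbols were named.

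Intensities were background-corrected with the normal-exponential model of limma 3.58.1 (R 4.3.3), with the negative control statistics inferred from the detection p-values and an offset of 16, then quantile normalized and log2-transformed. A gene was represented by its brightest probe with a detection p under 0.01 on both arrays, which gave 8661 genes, 6759 with 1 such probe and 1902 with 2 or more. Each difference is the log2 level on the SCTR siRNA array minus that on the negative control siRNA array. With 1 array per group no p-value was computed across genes, and genes at least 2-fold apart were counted by size alone. For a gene detected on 1 array only, the bright level was set against the higher of the dim probe's own level and the lowest level of a detected probe on the dim array, and the difference is given as at least that many fold.

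Before the data were examined, 34 gene lists were fixed, with the groups, the main settings and the rule for named genes. The cell cycle lists were chosen partly because the study's interest in the cell cycle was known from memory of its paper. For each list the median difference over members detected on both arrays was computed, with a 95% interval from 1000 bootstrap draws over members. Its percentile was taken among 10000 random lists of the same size matched on mean level in 20 bins, as a description of these 2 libraries and not of the conditions. A list was called outside the random range where its median lay outside their central 95%, and lists with fewer than 5 measured members got no percentile. In none of the 29 remaining lists did median and mean differ in sign, with the reference genes at a median of 0.00. Named genes were SCTR, the 12 largest positive and 12 largest negative differences at a mean log2 level of at least 7, the 4 genes with the largest bound in each direction, and up to 4 members of each list with the largest absolute difference. LBR, CENPF, VIM, ACTA2, LOX, HES1, HES2, ZNRF3 and DKK1 were named after their values were seen.

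The steps were tested on simulated data made from the mean of both arrays with a small noise set by hand. For the comparison of SCTR siRNA with control siRNA, 50 probes each with true log2 differences of -2, -1, 1 and 2 among 47316 probes gave medians of -1.93, -0.91, 0.97 and 1.98, all with the right sign. Of 14043 unchanged detected probes 4 came out at least 2-fold apart, and with random differences over 8661 genes 2 of 29 lists lay outside the random range. That simulation holds no spread between cultures.

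Alternatives were no background correction, a normal-exponential correction with offset 50, median scaling in place of quantile normalization, the authors' processed values, a detection p under 0.05, no detection filter, the mean over all detected probes of a gene, a 1.5-fold rule, a level minimum, and members detected on 1 array set at their bound. The setting with no detection filter still held only named probes, each with a detection p under 0.05 on at least 1 array. Removal of a lowess trend of the difference on level (span 0.3) was added after seeing the data. The alternatives planned for the SCTR level gave no value, because no named probe stood for it. Transcript lengths and siRNA sequences were not used here. Tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.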

Results

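Gene expression was measured in MCF-10A cells, a non-tumorigenic human mammary epithelial line, after transfection with a small interfering RNA (siRNA) against SCTR or with a negative control siRNA. SCTR encodes the secretin receptor, a G protein-coupled receptor that signals through cyclic AMP. Each group had 1 Illumina bead array, hybridised with biotin-labelled cRNA, so no difference could be set against a spread between replicates, no test was made, and the number of arrays limits the precision of each value. The arrays held signals for 47316 probes, with a mean of 711 and a median of 122 intensity units on the control array and a mean of 695 and a median of 124 on the SCTR siRNA array. At a detection p under 0.01, 15229 probes (32.2%) were detected on the control array and 15848 (33.5%) on the SCTR siRNA array. The 14243 probes detected on both correlated between the arrays with r = 0.922 across probes, which are not independent replicates.

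The comparison asked how transcript levels in these cells differed between SCTR knockdown and the control siRNA. The number of probes named SCTR was 0, so the level of the targeted gene was not checked, and each direction given here rests on the labels of the 2 arrays. Only probes of the authors' processed table could carry a name, and 3808 of those had none. Whether an unnamed probe stands for SCTR, and whether SCTR was detected in these cells, is therefore not known.

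A mixed list of Notch and Wnt genes, led by Notch receptors and ligands, was higher on the SCTR siRNA array. So were TGF-beta-related, basal epithelial and antioxidant genes, while cell division, histone, interferon-response and ribosomal protein genes were lower. The largest positive difference was that of F3, the tissue factor that starts blood coagulation, at 4.94 on the log2 scale (30.8-fold). FZD4, a receptor for Wnt ligands and norrin, was at -4.13, a level 17.5-fold higher on the control array, and the chemokine gene CCL5 at -4.10, further from 0 than FZD4 under median scaling, both other background treatments and in the authors' values. Among 8661 genes with a probe detected on both arrays, 844 were at least 2-fold higher and 731 at least 2-fold lower on the SCTR siRNA array, and the median difference was -0.09 (SD over genes 0.80). The lower count was 417 without background correction and 394 in the authors' values, which carry none.

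Next to F3, the largest positive differences among genes with a mean log2 level of at least 7 belonged to CSF1R (4.57), the receptor for colony-stimulating factor, CXCL8 (4.03), a chemokine that attracts neutrophils, and HBEGF (4.02), a ligand of the EGF receptor. ABCA12, a lipid transporter of keratinocytes, was at 3.78, the adhesion receptor ADGRG1 at 3.76 and matrix Gla protein (MGP) at 3.54. MLLT11 (3.35), the retinaldehyde reductase DHRS3 (3.31), the cornified envelope gene SPRR1A (3.29), the secreted glycoprotein STC1 (3.29) and the mitochondrial carrier SLC25A24 (3.20) completed the 12. A second probe gave 4.48 for CXCL8 and 3.72 for ADGRG1, but -0.38 for SLC25A24. CSF1R and HBEGF lay close to background on the control array, and their differences were 3.49 and 2.99 without background correction. MGP, MLLT11 and SLC25A24 were dim on that array too, and were at 2.70, 2.46 and 2.44 without it.

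At the other end, the level of CCL5 was 17.2-fold higher on the control array, and its second probe gave -3.94. NME4, a mitochondrial nucleoside diphosphate kinase, followed at -4.08, TENT5C, a non-canonical poly(A) polymerase, at -3.99, and the type III interferon gene IFNL1 at -3.70. The ethanolamine kinase gene ETNK2 was at -3.36, OXLD1 at -3.25 (second probe -0.97), the replicative helicase component CDC45 at -3.18 and the DNA topoisomerase TOP2A at -2.93. SNCAIP (-2.85), the interferon-inducible acyltransferase gene PLAAT4 (-2.83) and DGCR6 (-2.83, second probe -2.92) were the remaining ones. TENT5C and CDC45 lay close to background on the SCTR siRNA array, with a detection p of 0.0091, and were at -2.74 and -2.03 in the authors' values. IFNL1, TOP2A and SNCAIP were dim on that array too, and were at -2.8, -2.17 and -2.12 in the authors' values.

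Other genes were detected on 1 array only, and their differences are bounds. On the SCTR siRNA array alone 440 genes were detected, 79 of them with a bound of at least 2-fold, led by the organic anion transporter ABCC2 (at least 15.8-fold higher), the cornified envelope gene SPRR1B (at least 8.0-fold), the metalloprotease ADAM19 (at least 7.47-fold) and the taurine transporter SLC6A6 (at least 6.14-fold). On the control array alone 323 genes were detected, 61 with such a bound. The meiotic recombination gene MND1 was at least 6.41-fold higher there, the innate immune receptor NOD1 at least 5.32-fold, the histone gene H3C4 at least 4.98-fold and the acetyl-CoA synthetase ACSS1 at least 4.70-fold.

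**Figure D1:**
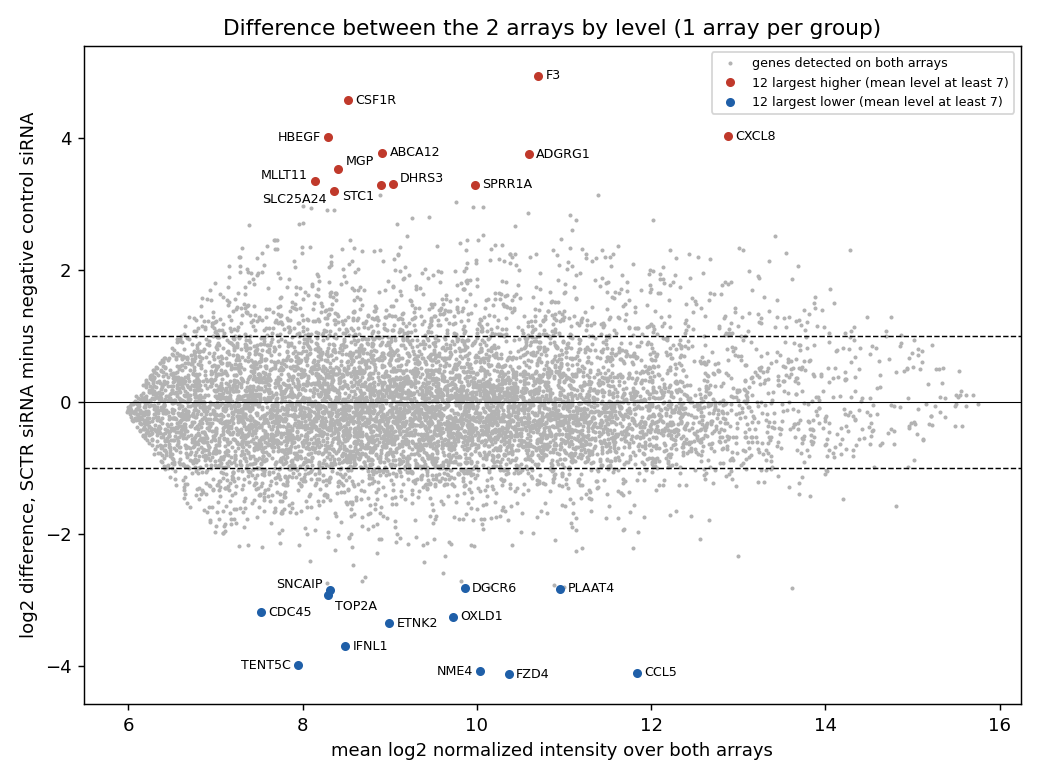
Each point is 1 of 8661 genes detected on both arrays, with its mean log2 normalized intensity on the x axis and its log2 difference, SCTR siRNA minus negative control siRNA, on the y axis. Dashed lines mark 2-fold, and the 12 largest differences in each direction among genes with a mean level of at least 7 are named, from F3 at 4.94 to FZD4 at -4.13.

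Genes of G2 phase and mitosis were lower on the SCTR siRNA array. Of 45 measured, 29 were at least 1.5-fold lower and 2 at least 1.5-fold higher, with a median of -0.81 (95% bootstrap interval over members -1.0 to -0.61), below every one of 10000 random gene lists matched on level. Besides TOP2A, the mitotic kinase CDK1 was at -2.41, the survivin gene BIRC5 at -1.97 (-1.09 in the authors' values) and the kinase cofactor CKS1B at -1.89 (second probe -1.91). The nuclear envelope gene LBR (1.22) and the kinetochore gene CENPF (1.19, and 0.69 in the authors' values) went the other way. The median was smaller in other treatments of background, at -0.47 without correction and -0.44 in the authors' values, still below the random range. It was also smaller in bright members, where 13 genes with a mean log2 level of at least 9 had a median of -0.27 (-1.17 to 0.27, percentile 20.2), inside the random range.

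S phase and DNA synthesis genes had a median of -0.55 over 24 members (-1.0 to -0.33), at percentile 0.31 of the random lists, with 11 at least 1.5-fold lower and 1 higher. CDC45 led them, followed by the DNA polymerase subunit POLD3 (-1.48), the chromatin assembly factor CHAF1B (-1.46) and the primase PRIM1 (-1.44, second probe -1.28). Most of these were dim, and in the authors' values POLD3 was at -0.92, CHAF1B at -0.72 and PRIM1 at -0.98. The 8 bright members had a median of -0.46 at percentile 8.03, inside the random range. Replication-dependent histone genes had a median of -1.07 over 11 members (-1.92 to -0.53), below every random list. Among them 8 were at least 1.5-fold lower and 0 higher, with H2AC6 at -2.72, H2BC21 at -1.93, H2BC5 at -1.92 and H4C14 at -1.74. Whether the lower histone values reflect fewer cells in S phase was not tested.

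Other lists of cell cycle control stayed within the random range. Origin licensing and firing genes, 7 of whose 16 measured members also belong to the S phase list, had a median of -0.22 (percentile 26.7). Below CDC45 their largest differences were those of the licensing inhibitor GMNN (-1.16), the helicase subunit MCM6 (-1.03) and ORC3 (-0.83). G1 cyclins, their kinases and E2F factors had a median of -0.07 over 12 members (percentile 49.4), with the ubiquitin ligase subunit SKP2 at -1.53 and CDK2 at -1.04 against CDK6 at 0.71. CDK inhibitors and pocket proteins, brakes of the cycle, had a median of -0.19 over 11 members (percentile 34.9), where the pocket protein RBL2 (-2.12), CDKN1C (-1.62) and BTG1 (-1.40) were lower and TOB1 (1.01) higher on the SCTR siRNA array.

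Targets of p53 showed no common direction, with a median of 0.02 over 22 members (percentile 70.4) whose sign depended on the detection filter. The stress cytokine GDF15 was at 2.83 and ZMAT3 at 1.88, while CCNG1 was at -2.26 and SESN1 at -2.17. The other probes of ZMAT3 gave 0.08 and -0.31. Apoptosis regulators had a median of -0.18 over 16 members (percentile 35.7), 7 of them at least 1.5-fold lower and 0 higher, including the BH3-only gene HRK (-2.20), the initiator caspase CASP9 (-1.98), BIRC5 and the effector caspase CASP6 (-1.13).

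Interferon-stimulated genes were lower on the SCTR siRNA array, 20 of 33 by at least 1.5-fold and 0 higher by that much. Their median was -0.67 (-0.74 to -0.47), below every random list, and 32 bright members gave -0.67 as well. The deISGylase gene USP18 was at -2.60, OASL at -2.33 (second probe -2.83), XAF1 at -1.88 (second probe -0.05) and the ISG15 ligase HERC5 at -1.23. Antigen presentation genes stayed within the random range at -0.24 over 15 members (percentile 18.1), and at -0.45 under median scaling (percentile 7.23). The immunoproteasome genes PSMB9 (-2.10) and PSMB8 (-0.94) were lower and ERAP2 (1.98) was higher, and the second probes of ERAP2 (-0.52) and of TAP2 (0.10 against -1.01) had the opposite sign. NF-kB and inflammatory genes had a median of 0.17 over 11 members (percentile 82.7) that spanned CXCL8 and CCL5, with ICAM1 at 0.80 and TNFAIP3 at 0.78.

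Genes of the cytosolic ribosome were lower on the SCTR siRNA array, with 40 of 42 negative and 26 within 1.5-fold. Their median was -0.55 (-0.62 to -0.39), below every random list, and 16 were at least 1.5-fold lower against 0 higher, among them RPL34 (-1.31), RPL24 (-1.30), RPL26 (-1.20) and RPS9 (-1.14). Mitochondrial respiration genes had a median of -0.41 over 31 members (-0.58 to -0.28), at percentile 0.995, with 10 at least 1.5-fold lower and 0 higher. The complex I subunit NDUFV1 was at -1.27, the complex III subunit UQCRB at -1.26, the complex II subunit SDHC at -0.81 and the ATP synthase subunit ATP5PO at -0.80. Transcript length was not analysed here for either list.

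**Figure D2:**
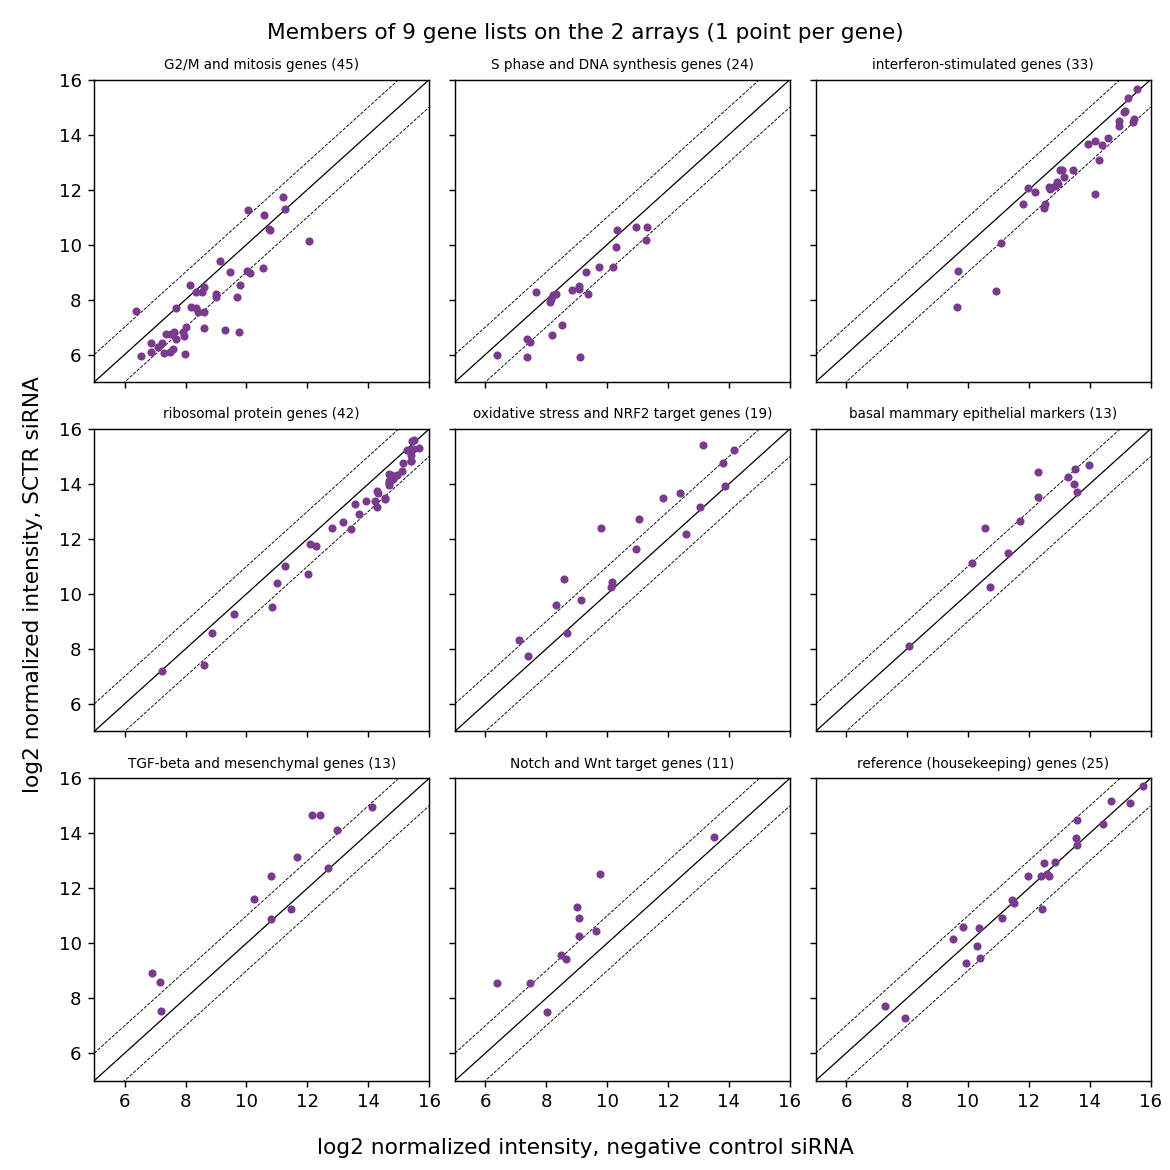
Each panel plots the members of 1 gene list detected on both arrays, 1 point per gene, with the log2 normalized intensity on the negative control siRNA array on the x axis and on the SCTR siRNA array on the y axis. The solid line marks equal levels and the dashed lines 2-fold, with 40 of 42 ribosomal protein genes under the solid line and 17 of 19 NRF2 target genes above it.

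Oxidative stress and NRF2 target genes were higher on the SCTR siRNA array, 12 of 19 by at least 1.5-fold and 0 lower by that much. Their median was 0.99 (0.27 to 1.29), above every random list. Thioredoxin reductase TXNRD1 was at 2.61 (second probe 2.5), the aldo-keto reductase AKR1C2 at 2.30, the glutathione synthesis enzyme GCLC at 1.98 and the quinone reductase NQO1 at 1.69. Unfolded protein and ATF4 response genes had a median of 0.46 over 25 members (0.07 to 0.76, percentile 99.6), with 10 higher and 2 lower by 1.5-fold or more. The endoplasmic reticulum chaperone PDIA4 (2.91), both subunits of a large neutral amino acid transporter, SLC7A5 (2.06) and SLC3A2 (1.70), and STC2 (1.71) led them. Heat shock and chaperone genes lay within the random range at 0.11 over 18 members (percentile 83.5), although the collagen chaperone SERPINH1 was at 2.25, BAG3 at 1.57, HSPA1A at 1.30 and HSPA1B at 1.19.

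Hypoxia and glycolysis genes had a median of 0.48 over 31 members at percentile 99.9, but the bootstrap interval reached from -0.04 to 1.19. Under median scaling the median was 0.24, still above the random range (percentile 98.8). Of these 13 were at least 1.5-fold higher and 1 lower, with hexokinase HK2 at 2.20, the glucose transporters SLC2A1 at 2.17 and SLC2A3 at 1.91, and the lipase inhibitor ANGPTL4 at 1.74. Cholesterol synthesis and SREBP target genes had a median of 0.30 over 24 members (0.06 to 0.57, percentile 98.3), 7 higher and 2 lower by 1.5-fold or more. HSD17B7 (1.37), the fatty acid desaturase FADS1 (1.31), acetyl-CoA carboxylase ACACA (1.27) and the transcription factor SREBF1 (1.00) were the largest. This list returned to the random range without background correction (percentile 97.2), with probes averaged per gene (median 0.18, percentile 94.6) and in its 20 bright members (97.4), as in other settings.

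Members of the TGF-beta and mesenchymal list were higher, 9 of 13 by at least 1.5-fold and 0 lower by that much, with a median of 1.36 (0.35 to 1.66) above every random list. The matrix glycoproteins thrombospondin THBS1 (2.51) and tenascin TNC (2.04), the protease inhibitor SERPINE2 (2.26) and S100A4 (1.66) led them, while the mesenchymal markers vimentin, VIM (0.04), and smooth muscle actin, ACTA2 (0.05), were near 0 and the lysyl oxidase LOX was at -0.24. Basal mammary markers had a median of 0.95 over 13 members (0.17 to 1.05, percentile 99.99), 8 of them at least 1.5-fold higher and 0 lower, including the laminin chain LAMB3 (2.14), EGFR (1.81, second probe 1.24), the integrin ITGA3 (1.20) and caveolin CAV1 (1.05). Epithelial junction and polarity genes had a median of 0.56 over 17 members (0.04 to 0.71, percentile 99.8), with 8 higher and 3 lower. E-cadherin, CDH1, was at 1.79, the membrane protease ST14 at 1.16 and P-cadherin, CDH3, at 0.99, against the epithelial transcription factor OVOL2 at -1.03.

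The list of Notch and Wnt genes had a median of 1.09 over 11 members (0.78 to 2.18, percentile 99.975), 9 of them at least 1.5-fold higher and 0 lower by that much. It was fixed as a list of targets, but 7 of its measured members are receptors or ligands, and no percentile was computed for either pathway alone. The 4 largest differences were the receptors NOTCH1 (2.75) and NOTCH3 (2.18) and the ligands JAG1 (2.33) and JAG2 (1.86, second probe 1.88), and among the others HES2 was at 1.19, ZNRF3 at 1.09, HES1 at 1.08 and DKK1 at 0.36. In all 10 members were positive and 1 negative, and the Wnt receptor FZD4, which is not in the list, was at -4.13. Luminal mammary markers lay within the random range at 0.50 over 9 members (percentile 95.4), with AGR2 at 2.26, CD24 at 1.15 and ELF3 at 0.77, while ERBB3 was at -0.67 by its brightest probe and 0.31 by the other. Squamous differentiation genes had a median of 0.08 over 10 members (percentile 68.6), with SPRR1A and CNFN (1.00) on 1 side and KLF4 (-1.20) and S100P (-1.02) on the other. EGFR and MAPK feedback and immediate-early genes had a median of 0.25 over 20 members (percentile 94.0), with HBEGF, PHLDA1 (2.96) and IER3 (2.19) higher and FOS (-1.97) lower.

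Genes that respond to cyclic AMP and CREB had a median of -0.24 over 17 members (percentile 21.5), within the random range. Their 11 bright members had a median of -0.72 (-1.20 to 0.38) at percentile 0.17, below it, and at a detection p under 0.05 the list was also below it, at -0.48 over 18 members (percentile 1.69). With the member detected on 1 array at its bound the median was -0.44. The G protein regulator RGS2 was at -2.81 and FOS at -1.97, while adrenomedullin, ADM, was at 1.49 and ID3 at 1.43. The cyclic AMP machinery had a median of 0.61 over 9 members at percentile 97.49, just inside the upper bound but outside it under 5 of the 8 alternatives that gave a percentile, with CREB1 at 1.40 (other probes 1.54 and -0.63), ADCY7 at 0.90 and CREBBP at 0.75, against the protein kinase A subunit PRKAR1A at -0.86. Of the secretin-family receptors and ligands 2 were measured, both near background on the control array, VIPR1 at 1.81 and CRHR1 at -0.01, with the other sign under median scaling.

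RNA interference and microRNA pathway genes had a median of -0.01 over 14 members (percentile 62.0), a sign that turned under median scaling and without background correction. The microRNA-processing nuclease DICER1 was at -1.62 (second probe -1.74) and AGO1 at -1.41, while TNRC6B was at 0.95 and TNRC6A at 0.77. The 25 reference genes had a median of 0.00 (-0.13 to 0.19, percentile 65.0), with VPS29 (-1.18) and CHMP2A (-0.92) lower and TFRC (0.91) and POLR2A (0.75) higher. Markers of other cell types were too few for a percentile. The endothelial marker ENG was at 1.34, the leukocyte markers CD14 at 1.78 and CD68 at -0.52, the adipocyte markers LEP at 2.45 and PPARG at -0.72, and 0 fibroblast markers were detected on both arrays.

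**Figure D3:**
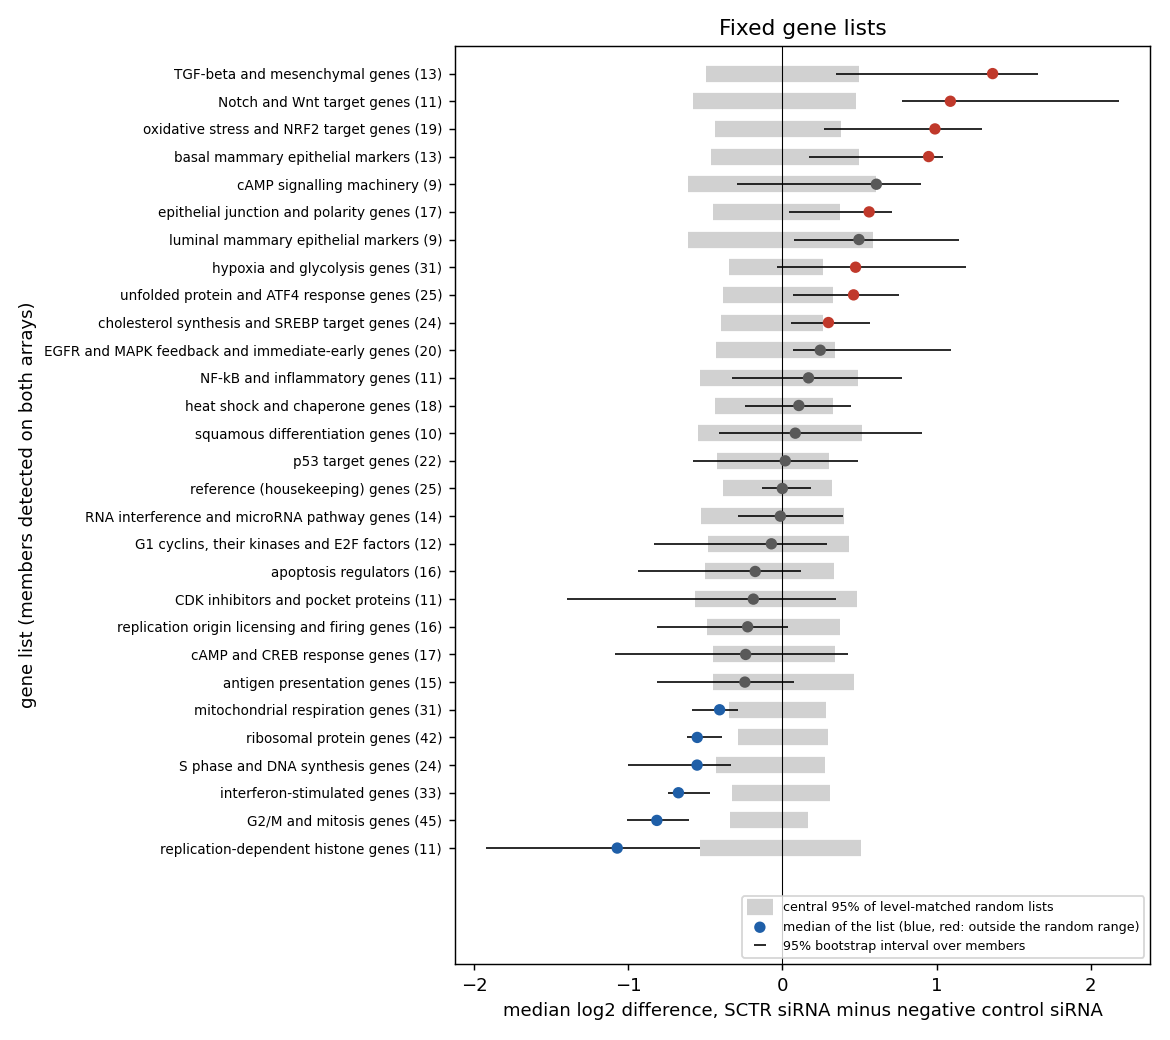
Points give the median log2 difference, SCTR siRNA minus negative control siRNA, of 29 gene lists, with their number of measured genes in brackets, thin lines its 95% bootstrap interval over members and grey bars the central 95% of 10000 level-matched random lists. In this view 6 lists lie below the grey bars (blue), down to -1.07 for histone genes, and 8 above (red), up to 1.36 for TGF-beta and mesenchymal genes.

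In all, 14 of the 29 lists with at least 5 measured members lay outside the central 95% of random lists, where 5% would for lists of independent genes, and members of a list are often regulated together. Different probes of a gene were the only repeat measurement within a sample. Of 328 genes with 2 or more detected probes and a brightest probe at least 2-fold apart, 295 (89.9%) had each other probe on the same side and 251 (76.5%) had each at least 1.5-fold apart. Across 1902 genes the brightest and the second probe correlated with r = 0.785 and rho = 0.802, and these share the RNA and the array, so the agreement does not stand in for replicates. Without background correction, 6 more genes close to background on 1 array were smaller by over 1.5 times, namely NOTCH3 (1.42), VIPR1 (1.16), CNFN (0.62), CDKN1C (-1.0), AGO1 (-0.86) and UQCRB (-0.82). LEP (1.66), TNC (1.46), AGR2 (1.63) and PDIA4 (2.20), dim on the control array, were smaller without it too.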

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

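The comparison of named with unnamed probes was chosen only after the results were seen. Probes without a gene name entered no gene count of the report, yet many differed between the arrays. Of 3366 such probes detected on both arrays, 441 were at least 2-fold higher and 304 at least 2-fold lower on the SCTR siRNA array, a share of 22.1% against 17.8% of 10877 named probes. Among the 1024 probes detected on both arrays and not used in the authors' processed table, 184 were at least 2-fold higher and 125 lower, 30.2% against 17.9% of the 13219 probes in it. All of these 1024 are unnamed, and the other 2342 unnamed probes had a share of 18.6% (257 higher, 179 lower), so the excess among unnamed probes lies in the 1024. The SD of the log2 difference was 1.14 in these 1024 and 0.80 in the probes of the table. No biological explanation of these shares was tested.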

How the results depend on the processing

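Removal of the level trend was chosen only after the results were seen, and the other alternatives were planned. No list outside the random range turned its sign under any of them, and of the 137 genes named by rule only CRHR1, at -0.01, did (0.08 under median scaling). Of the genes named later, VIM went from 0.04 to -0.06 under median scaling. Bounds were not recomputed. The higher count stayed within 1.5 times of 844 throughout, apart from the 1.5-fold rule itself, which gave 1693 higher and 1955 lower. The count of genes at least 2-fold lower went from 731 to 417 without background correction, 476 with an offset of 50 and 394 in the authors' values, and the median of the G2 phase and mitosis genes went from -0.81 to -0.47, -0.53 and -0.44. Less background subtraction compresses dim probes by construction, and 32 of these 45 genes had a mean log2 level under 9. Under median scaling the medians of interferon-stimulated and ribosomal protein genes were further from 0, at -0.76 and -0.75, that of hypoxia genes was nearer, at 0.24, as was that of cholesterol synthesis genes with probe means, at 0.18, and the cause was not tested. No scaling moved the median of all genes by over 0.1. Of the 14 lists outside the random range, 13 or all 14 stayed outside on the same side under each alternative with a percentile, and the one lost was cholesterol synthesis, without background correction, with an offset of 50, under median scaling, in the authors' values, with probe means and with the level trend removed. Among lists within the random range, medians of the licensing, CDK inhibitor, apoptosis, antigen presentation, NF-kB, luminal and both cyclic AMP lists and of lists nearer 0 moved by over 1.5 times under at least 1 alternative. The cyclic AMP machinery was outside with median scaling, a detection p under 0.05, no detection filter, probe means and the level trend removed, the luminal markers without background correction, under median scaling and in the authors' values, and the cyclic AMP response genes at a detection p under 0.05. Medians of p53 targets (-0.06 to 0.13), RNA interference genes (-0.11 to 0.09) and reference genes (-0.08 to 0.10) lay on both sides of 0. Of 137 differences of named genes, 27 moved by more than the spread between probes without background correction, 27 in the authors' values, 18 with an offset of 50 and 8 with probe means. At a detection p under 0.05 the share of genes with each probe on the same side was 87.8% against 89.9%. The SCTR alternatives gave no value. Signal over background limits the dim genes, since the lowest detected level was 6.04 on the control array and 5.91 on the other.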

Other observations

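All tests in this part, the scan of symbol families and the choice of IFNB1 and DGCR6L were chosen only after the results were seen, the test on dim members after that on bright ones. Genes whose symbols share a root were grouped into 95 families of at least 10 measured members, and 17 had a median outside the central 95% of level-matched random lists, against 4.8 expected for independent genes. Solute carriers (SLC), the membrane transporters, stood out above, with a median of 0.54 over 157 members, above every random list, and 77 at least 1.5-fold higher against 16 lower. The SNORA family of small nucleolar RNA genes had a median of 0.47 over 22 members, 9 of them at least 1.5-fold higher and 0 lower. The HSPA chaperones (median 0.60 over 12), the ALG glycosylation genes (0.44 over 12), the TMEM genes (0.14 over 125) and the CD antigens (0.29 over 24) were above as well, the last of these at percentile 97.7 and back inside the random range (96.4) with the level trend removed, and at a median of 0.16 under median scaling.

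Below the random range, mitochondrial ribosomal proteins had medians of -0.49 over 49 MRPL genes and -0.51 over 28 MRPS genes, beside -0.56 over 55 RPL and -0.46 over 36 RPS symbols. All 10 COMMD genes, which act in endosomal trafficking, were at least 1.5-fold lower on the SCTR siRNA array, with a median of -0.72, and 7 of 10 CHMP genes of the ESCRT membrane-remodelling machinery were, with a median of -0.78. The vesicle-sorting VPS genes (-0.51 over 32), RAB GTPases (-0.41 over 46), RNF ubiquitin ligases (-0.39 over 51) and IFT genes of ciliary transport (8 of 12 at least 1.5-fold lower) were also below. These families kept their sign under each scaling, but the RNF median was -0.24 without background correction and -0.22 in the authors' values. Transcript length was not analysed here. Beside IFNL1, the type I interferon gene IFNB1 was at -2.25, a level 4.75-fold higher on the control array, and DGCR6L, the close paralog of DGCR6, was at -2.48.

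Genes of G2 phase and mitosis were lower on the SCTR siRNA array. All genes, put in 10 groups by signal level, had medians between -0.12 and -0.05, which argues against a level trend as the whole cause. The median of -0.70 left after the trend was removed adds little, since the random lists were already matched on level. The dim members had a median of -0.82, but they are 32 of the 45 genes, so this nearly repeats the list median. The bootstrap interval of the dim members, -1.09 to -0.70, lay below the random range of -0.41 to 0.20 for lists matched on level. Such lists share the background noise of dim probes. These values therefore argue against that noise as the whole cause in the dim members. Faulty single probes are argued against by the other probes of 11 of these genes, with a median of -0.95 and 9 negative. A shift present only in dim members stays open, since the 13 bright ones had a median of -0.27 with an interval that includes 0 and the dim value, and so does an error with the 2 samples exchanged, since 0 probes named SCTR were there to check it and the paper's title, recalled from memory and not checked, gives SCTR an anti-proliferative role in normal breast cells. Fewer dividing cells in the SCTR siRNA culture may be the cause, but with 1 array per group loss of SCTR, off-target effects of the siRNA (here and for the other lower genes) and a difference between the cultures, such as density, cannot be told apart.

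Interferon-stimulated genes were lower on the SCTR siRNA array together with IFNB1, IFNL1 and CCL5. Of the 33 interferon-stimulated genes, 32 had a mean log2 level of at least 9 over both arrays. For example, ISG15 was at 15.45 on the control array and 14.58 on the other, and MX1 at 15.17 and 14.87. After the level trend was removed the median of the list was -0.66, which adds little because the random lists were already matched on level. The small medians of all genes grouped by level (-0.12 to -0.05) argue against a level trend as the whole cause. The other probes of 12 of these genes were all negative with a median of -0.79, which argues against faulty single probes as the whole cause. Short double-stranded RNA can itself start an interferon response, so a response to the control siRNA itself may lie behind the difference as well as a lower response with SCTR siRNA. With 0 arrays of untransfected cells these cannot be told apart.

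Ribosomal protein genes were lower on the SCTR siRNA array, with 40 of 42 negative. The median after removal of the level trend was -0.57, which adds little because the random lists were already matched on level. The small medians of all genes grouped by level (-0.12 to -0.05) argue against a level trend as the whole cause. The other probes of 14 genes were all negative with a median of -0.81, which argues against faulty single probes as the whole cause. Slower growth of the SCTR siRNA culture is a candidate explanation that was not tested. RNA integrity or labelling that differed between the extracts also stays open, here and for the mitochondrial, COMMD and CHMP genes, because it could act unequally on short and long transcripts, and transcript length was not analysed here. Median scaling gave -0.75, so the size of the shift depends on the normalization.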
